A study of Mus musculus with 20 samples.

How the data were processed

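RNA was measured by strand-specific sequencing of polyadenylated transcripts from 20 spleens of mice carrying a transplanted mouse T-cell acute lymphoblastic leukemia. In these leukemias Acly can be deleted with tamoxifen, so the knockout groups received tamoxifen (3 mg per mouse) and the control groups received corn oil alone. Spleens were pressed through a filter and red cells were lysed. No sort for leukemic cells is named in the labels, so each library holds the RNA of the whole suspension. The labels give one library per replicate number and different animal codes per library. They do not state outright that each library is a separate mouse, so the p-values measure the spread between libraries.

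The authors deposited 2 tables, each with one column of DESeq-normalized counts per library. These values are a signal of normalized counts in the deposited tables, not raw reads: they are not whole numbers, and each table was scaled on its own. Per the submitters' processing notes, transcripts were quantified with kallisto 0.46.0 against the mouse genome build GRCm39 and normalized with DESeq. The annotation, the step from transcripts to genes and any filter are not given in the sources used here. Low values clustered at multiples of a step that differed between libraries and varied by gene, and 52.2 to 82.4% of them lay within 0.1 of a step of a whole multiple. Whole reads were therefore not recovered, and tests that need them were not run. A single step per library is therefore in doubt. Taken as 1 read, the most frequent step would put the depth at 16.6 to 23.7 M reads per library, a rough figure. Genes are identified by symbol only, and no coordinates are given because the reference held here is of another genome build.

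From the deposited values, log2(normalized count + 1) was computed. A gene was tested where its normalized count reached 10 in at least 4 libraries of the acute table or 5 of the survival table, the size of the smaller group. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with group means and no block or covariate. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Acly was also compared by an exact two-sided permutation test of the mean log2 value. The contrast between the tables, the survival fold change less the acute fold change, was fitted over all 20 libraries on genes tested in both, so that each fold change stayed within its own table. On simulated data with the sizes of these groups, the same fit recovered 32% of 50 genes changed by 1.25-fold, 80.0% at 1.5-fold, 96% at 2-fold and 100% at 4-fold in the acute design. In the survival design it recovered 18% of 50 genes at 1.25-fold, 68% at 1.5-fold, 86% at 2-fold and 100% at 4-fold. In those simulations 9 of 163 called genes in the acute design and 4 of 140 in the survival design had not been changed. Changed genes were drawn from those with a control mean of at least 50, and all fold sizes were changed at once. Genes were simulated independently, with a spread taken from the controls alone. Recovery in the real tables, where knockouts may vary more and fewer genes may change, can therefore be lower. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.

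Gene lists, comparisons, tests and most alternatives were chosen before the data were examined. The 29 lists cover acetyl-CoA and citrate supply, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, targets of the sterol sensor LXR, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded transcripts, NOTCH targets, MYC targets, the cell cycle, p53 targets, the integrated stress response, the unfolded protein response, interferon response, histone acetylation enzymes, immediate early genes, replication-dependent histone genes and sex-linked genes. They also hold markers of T cells and thymocytes, B cells, plasma cells, monocytes and macrophages, neutrophils, erythroid cells, dendritic cells, NK and cytotoxic cells, stroma and endothelium, and megakaryocytes. Ptcra (NOTCH and T-cell lists) and Xbp1 (unfolded protein response and plasma-cell lists) each stand on 2 lists, and every other listed gene stands on one. Lists were tested with camera (limma, preset correlation 0.01, Benjamini-Hochberg over the lists). Beside it stand camera with a correlation estimated from the data and fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. In the text, a list is called when its adjusted p by camera with the preset correlation is under 0.05. Markers are reported as markers only, never as shares of cells.

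Genes were named by a fixed rule. Acly, Acss2, Fasn, Srebf1, Srebf2, Notch1, Hes1, Dtx1 and Myc were always named. To these were added the 8 largest rises and the 8 largest falls per comparison among called genes with a mean of at least 100 in the higher group and no overlap between groups, leaving out predicted genes and receptor segments. From each list that was called or held 3 or more called members, up to 3 called members with the smallest p qualified. The text names the first members of these by p, a narrowing chosen after the values were seen. For the contrast between the tables, the 5 genes with the smallest p in each direction were named. Some genes that the rule picks are not reported here. Ngp, S100a9, Gzma, Hilpda, Trbv1, Trbv26, Scart1, Eci1, Acadl, Edem1, Mcm6, Cd163, Vcam1, Mrc1, Csf1r and Hmox1 fall outside the rule and were chosen after their values were seen.

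Alternatives changed one choice at a time: the pseudocount (0.1 or 8), the filter (none, or 50), the threshold (adjusted p under 0.01, or a fold of at least 2), rescaling to the same total, quantile normalization, robust eBayes, array weights, the replicate number as a block, a score of markers of other cell types as a covariate, and leaving out each library in turn. After the data were seen, 3 choices were added. Each library was scaled by the mean of 4 T-cell receptor beta genes of the leukemia (Trbc1, Trbc2, Trbv26 and Trbv2). Acute knockout libraries 2 and 3, which hold the highest levels of markers of other cell types, were left out together. Camera was also run on the contrast between the tables. The marker score is the mean of the standardized mean log2 values of the lists of other cell types.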

Results

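Acly encodes ATP-citrate lyase, the enzyme that splits cytosolic citrate into acetyl-CoA and oxaloacetate. Its acetyl-CoA feeds fatty acid and sterol synthesis and protein acetylation. RNA was sequenced from 20 leukemic spleens in 4 groups. In the acute arm, mice with overt leukemia received corn oil (6 control libraries) or tamoxifen (4 knockout libraries), and spleens were taken 72 h later. In the survival arm, mice received corn oil (5 control libraries) or tamoxifen (5 knockout libraries) 48 h after transplantation, and spleens were taken at the humane endpoint. The acute arm asks what follows soon after Acly is deleted in an established leukemia. The survival arm asks what distinguishes leukemic spleens at the endpoint after early deletion. How many independent leukemias the mice received was not tested, so the p-values cannot be read as a spread between independent leukemias. Control means the same conditional leukemia without tamoxifen, so tamoxifen and deletion cannot be separated by these groups. Totals of normalized counts ranged from 19432235 to 20731983 per library in the acute table and from 19998354 to 21623571 in the survival table. The acute table listed 26099 genes, of which 16363 were tested, and the survival table listed 26486, of which 16136 were tested.

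Acly RNA was lower in both knockout groups and was not lost in either. In the acute arm it fell from 7735 ± 298 normalized counts (SD, n = 6) to 5670 ± 766 (n = 4), which is 73.3% of control (log2 fold change -0.46, SE 0.0747, adjusted p = 0.000866; exact two-sided permutation p = 0.00476, the smallest that 210 arrangements can give). In the survival arm it fell from 7889 ± 561 (n = 5) to 3091 ± 712 (n = 5), 39.2% of control (log2 fold change -1.38, SE 0.131, adjusted p = 0.0016; exact two-sided permutation p = 0.00794, the smallest that 252 arrangements can give). The survival fall was the larger one by 0.92 on the log2 scale (difference -0.92, SE 0.164, adjusted p = 0.000442). Knockout libraries did not overlap with controls in either arm. The labels do not say which exons are removed, so reads from the rest of the transcript still count towards Acly. The acute fall passed the threshold under 21 of 22 alternatives. It was -0.72 (SE 0.122, adjusted p = 0.033) with the score of other cell types as a covariate, -0.62 (SE 0.0554, adjusted p = 0.000141) without knockouts 2 and 3, and -0.069 (SE 0.154, adjusted p = 0.727) when libraries were scaled to the T-cell receptor beta genes of the leukemia. The survival fall passed under all 21 alternatives. The difference between the arms was -0.66 (SE 0.259, adjusted p = 0.334) with the score of other cell types as a covariate, within a range of -1.26 to -0.66 over 32 alternatives.

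**Figure D1:**
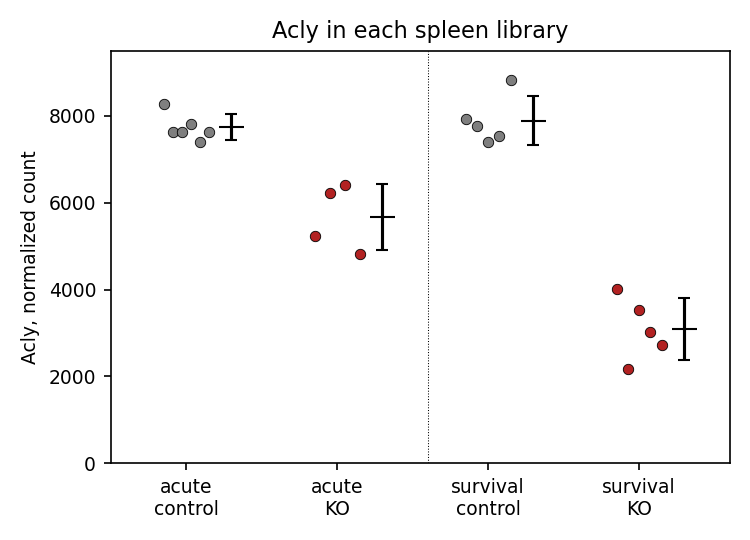
Acly normalized counts per library (y axis, from 0) in the 4 groups (x axis), with the mean and SD of each group. Acute knockout libraries lie between 4823 and 6402 against 7406 to 8280 in acute controls, and survival knockout libraries between 2174 and 4017 against 7396 to 8825 in survival controls; scaled to T-cell receptor beta genes, the acute log2 difference is -0.069.

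In the acute arm, markers of myeloid, B-lineage and cytotoxic cells and interferon-induced genes were higher in knockout spleens, while T-lineage genes, MYC targets and oxidative phosphorylation genes were lower as deposited, turning to higher medians after scaling to T-cell receptor beta genes. limma called 5140 of 16363 genes: 2731 were higher and 2409 lower in the knockout. Changes of at least 2-fold were mostly rises, with 1356 genes higher and 70 lower. The groups did not overlap for 3708 genes, 22.7% of those tested, where chance gives 0.95%. The direction of small changes depends on scaling. Scaling to T-cell receptor beta genes, which averaged -0.39 (log2) in the knockout, raised all fold changes by 0.39 and gave 7094 genes higher and 69 lower, while quantile normalization moved the median of all genes by -0.11 and gave 2318 higher and 4145 lower. The score of other cell types ranged from -0.82 to -0.12 in acute controls and from 0.11 to 1.53 in acute knockouts, highest in knockouts 2 (1.53) and 3 (1.27). With that score as a covariate limma called 150 genes, and without knockouts 2 and 3 it called 2137.

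Camera called 17 of 29 lists, 12 higher and 5 lower. With an estimated correlation it called 0, also 0 at an unadjusted p under 0.05, while fry called 18. Neutrophil markers had the largest median of the 29 lists. All 18 rose, with a median log2 fold change of 3.72, a 13.2-fold rise (adjusted p = 1.14e-14; adjusted p = 0.367 with an estimated correlation). Mmp9, a granule gelatinase, rose from 285 ± 88.8 to 7840 ± 5220 normalized counts, and Mmp8, the neutrophil collagenase, from 103 ± 42.9 to 2908 ± 1870 (SD, n = 6 and 4). The most abundant markers were the granule protein gene Ngp, which rose from 7157 ± 3660 to 95890 ± 54900, and S100a9, a subunit of calprotectin, which rose from 4754 ± 2470 to 62210 ± 33600. Monocyte and macrophage markers rose for 19 of 20 (median 0.96, adjusted p = 8.61e-10; adjusted p = 0.367 with an estimated correlation). Ccr2, the receptor that brings monocytes out of the marrow, rose by 4.36 (SE 0.349), and Ly6c2, a marker of inflammatory monocytes, by 4.17 (SE 0.416).

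B-cell markers rose for 16 of 17 (median 1.33, adjusted p = 9.39e-08; adjusted p = 0.367 with an estimated correlation), among them the invariant chain gene Cd74 (1.53, SE 0.221) and the B-cell receptor regulator Cd22 (1.67, SE 0.256). Plasma-cell markers rose for 7 of 9 (median 1.08, adjusted p = 0.000871; adjusted p = 0.367 with an estimated correlation), including Jchain, which joins secreted antibodies (2.0, SE 0.25), and the coactivator Pou2af1 (1.30, SE 0.185). Of 110 tested immunoglobulin segments 86 rose and 0 fell. Of all 161 tested receptor segments 86 rose and 19 fell, so every fall lay among the T-cell receptor segments and every rise among the immunoglobulin ones. NK and cytotoxic markers rose for 9 of 11 (median 2.09, adjusted p = 5.1e-05; adjusted p = 0.367 with an estimated correlation), such as the granule genes Nkg7 (2.80, SE 0.368) and Gzmb (3.35, SE 0.442). Gzma went the other way and fell from 7725 ± 635 to 5895 ± 717, a fall of -0.39 (SE 0.0836) that was -0.0054 after scaling to T-cell receptor beta genes and not called without knockouts 2 and 3 (adjusted p = 0.0793). Its level in controls was far above that of Nkg7 (57.8 ± 34.1) and Gzmb (19.4 ± 6.35). Dendritic markers rose for 6 of 10, and for 8 adjusted over the list alone (median 1.41, adjusted p = 0.00015; adjusted p = 0.367 with an estimated correlation), led by Clec10a (2.95, SE 0.467) and the cytokine receptor gene Flt3 (2.04, SE 0.33). Counts adjusted over the list alone were 18 for neutrophil, 19 for macrophage, 16 for B-cell, 7 for plasma-cell and 10 for NK markers. The marker score does not overlap between the acute groups, and the neutrophil, macrophage, B-cell, plasma-cell, NK and dendritic lists kept an adjusted p under 0.05 without knockouts 2 and 3, with lower medians and, except for neutrophils, fewer markers called. The medians were then 3.14 (18 of 18 markers called), 0.62 (10 of 20), 1.05 (8 of 17), 0.545 (2 of 9), 1.5 (4 of 11) and 1.13 (4 of 10), in that order. With the marker score, which holds these lists, as a covariate, the B-cell (adjusted p = 0.0605), plasma-cell (0.167) and dendritic lists (0.497) lost their calls, while the neutrophil (median 1.82, 7 of 18 markers called), macrophage (0.26, 1 of 20) and NK lists (0.945, 0 of 11) were still called.

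Less uniform were the megakaryocyte, erythroid and stromal markers. Of 7 megakaryocyte and platelet markers 2 rose, the integrin gene Itga2b (1.08, SE 0.299) and Vwf, von Willebrand factor (1.15, SE 0.369). The megakaryocyte median was 1.00 (adjusted p = 0.0483; adjusted p = 0.499 with an estimated correlation). With the marker score as a covariate it was -0.33, and it was not called without acute control 1, 3, 5 or 6 (adjusted p 0.0753, 0.0637, 0.0581 and 0.0561) or knockout 1, 2 or 3 (0.0653, 0.091 and 0.128). Itga2b was also not called without knockout 2 or 3 (adjusted p 0.0603 and 0.0602), nor Vwf without control 3, 5 or 6 (0.0666, 0.0659 and 0.0584) or knockout 2 or 3 (0.111 and 0.103). Without both knockouts Itga2b was 0.621 and Vwf 0.584, and with the marker score as a covariate they were -0.192 and -0.125. All 18 erythroid markers had positive fold changes and limma called 0 of them, 7 at an unadjusted p under 0.05 (median 0.55, adjusted p = 0.0148; adjusted p = 0.606 with an estimated correlation; fry adjusted p = 0.153). The erythroid call was lost without knockout 2 (adjusted p = 0.091) or knockout 3 (0.0996), the median was 0.019 without both, and with the marker score as a covariate the list was called lower (median -0.77, adjusted p = 2.45e-07). Stroma and endothelium markers were not called, with 1 of 12 higher and a median of 0.063 that was -0.16 after quantile normalization (adjusted p = 0.794).

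**Figure D2:**
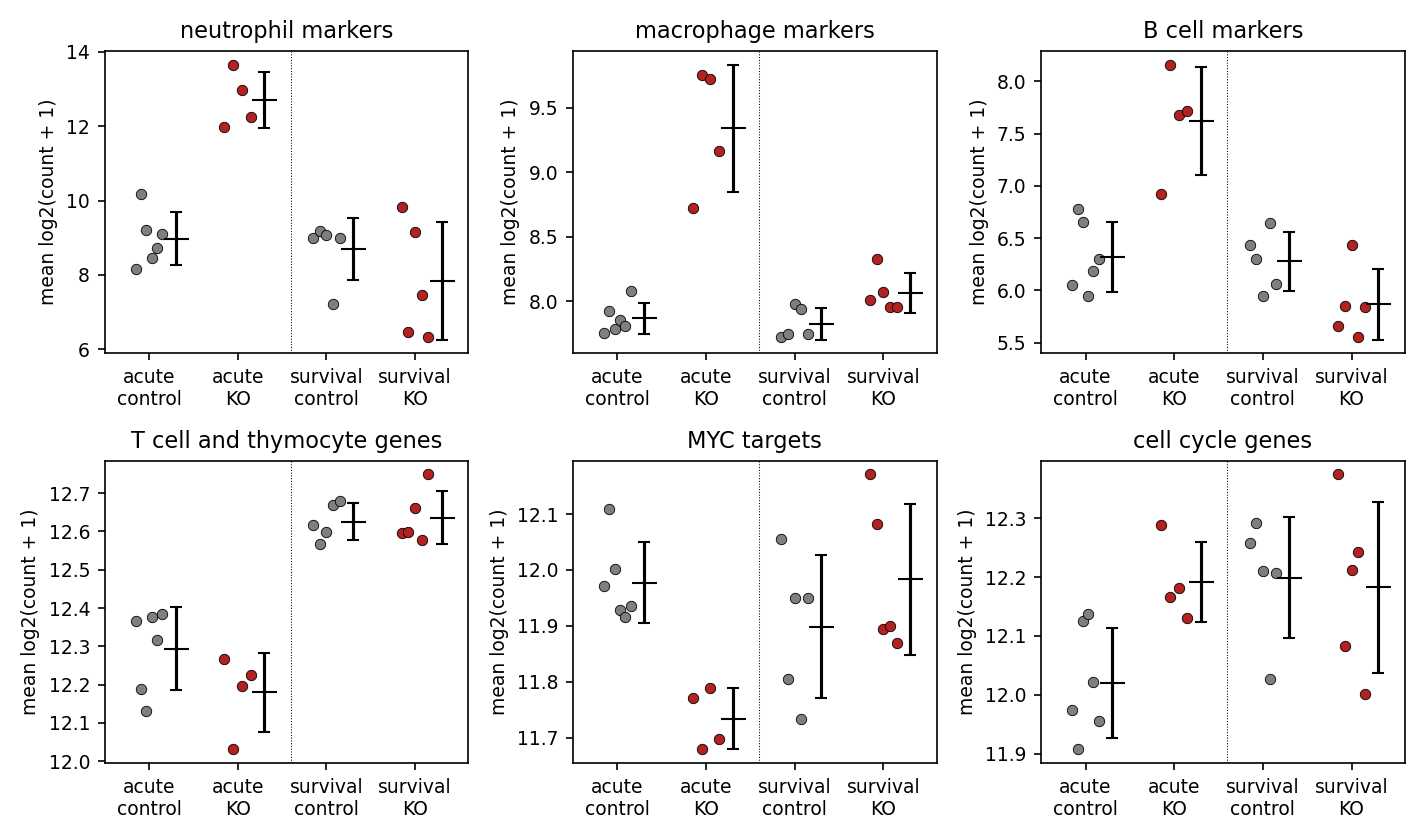
Mean log2(normalized count + 1) of 6 gene lists (y axis) in each library of the 4 groups (x axis), with group mean and SD. Neutrophil, macrophage and B-cell means are higher in acute knockouts, with medians of members of 3.72, 0.96 and 1.33; T-cell and MYC lists are lower by -0.34 and -0.23 as deposited but higher by 0.049 and 0.16 after scaling to T-cell receptor beta genes, and the cell cycle list is higher by 0.24.

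Interferon-response genes rose for 20 of 25, and for 22 adjusted over the list alone (median 1.16, adjusted p = 8.61e-10; adjusted p = 0.367 with an estimated correlation). Oasl2 and Oas2, antiviral genes of the oligoadenylate synthetase family, rose by 4.29 (SE 0.418) and 3.70 (SE 0.357), from 21.9 ± 8.17 to 517 ± 327 and from 76.0 ± 24.2 to 1119 ± 660 normalized counts. The interferon median was 0.80 without knockouts 2 and 3, with 13 of 25 called and an adjusted p of 7.16e-10, and 0.16 with the marker score as a covariate, with 2 of 25 called and an adjusted p of 0.0231. Genes of the unfolded protein response, which expands folding capacity in the endoplasmic reticulum, rose for 13 of 18 (median 0.25, adjusted p = 0.000756; adjusted p = 0.497 with an estimated correlation; 13 adjusted over the list alone). Sel1l, part of the ER degradation machinery, rose by 0.34 (SE 0.0598) and the stress sensor Atf6 by 0.64 (SE 0.141). Without knockouts 2 and 3 the median of this list was 0.13 with 1 of 18 called (list adjusted p = 0.0172), and Atf6 was 0.36 and not called (adjusted p = 0.0709). With the marker score as a covariate the median was -0.037 and the list was not called (adjusted p = 0.896). Edem1, which sends misfolded glycoproteins to degradation, was lower (-0.24, SE 0.0823), although 0.15 after scaling to T-cell receptor beta genes and 0.085 with the marker score as a covariate. Its call was lost without control 2, 3, 4, 5 or 6 or knockout 2 or 3, at adjusted p-values of 0.0618 to 0.147.

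Cell cycle genes rose for 13 of 30 and 1 fell (median 0.24, adjusted p = 0.0258; adjusted p = 0.519 with an estimated correlation). Adjusted over the list alone, 14 rose and 2 fell. Without knockouts 2 and 3, and also with the marker score as a covariate, 4 rose and 0 fell, with the list still called (adjusted p = 0.0172 and 5.84e-05). Mki67, the proliferation antigen Ki-67, rose from 14770 ± 1730 to 22180 ± 1540 (0.59, SE 0.0848) and the mitotic kinase gene Plk1 by 0.52 (SE 0.0903). Mcm6, of the replicative helicase, was lower (-0.17, SE 0.0548) and was 0.21 after scaling to T-cell receptor beta genes. Mcm6 was not called without control 2, 4 or 6 (adjusted p 0.0574, 0.0593 and 0.0562) or knockout 2, 3 or 4 (0.0908, 0.065 and 0.0642). The list was not called without control 1 (adjusted p = 0.0659) or knockout 1 (0.174). Of 13 mitochondrially encoded transcripts 1 rose, mt-Co1, a cytochrome oxidase subunit (0.36, SE 0.102), and 0 passed adjusted over the list alone, against 7 at an unadjusted p under 0.05. Their median was 0.20 (adjusted p = 0.039; adjusted p = 0.606 with an estimated correlation). That call was lost without control 1 or 2 (adjusted p 0.0963 and 0.0755) or knockout 1 or 4 (0.0923 and 0.21), and mt-Co1 was not called without knockout 3 or 4 (0.0547 and 0.0543) or without knockouts 2 and 3 (0.105).

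The stress lists moved in mixed directions and were not called. Of 18 tested genes of the integrated stress response 4 rose and 2 fell (median 0.11, adjusted p = 0.335), with rises of the transcription factor gene Cebpb (1.52, SE 0.224) and Chac1, which degrades glutathione (2.51, SE 0.529; 1.89 and not called without knockouts 2 and 3, adjusted p = 0.0793), from 5.94 ± 4.54 to 38.5 ± 28.8 normalized counts. Immediate early genes rose for 7 of 18 and 1 fell (median 0.23, adjusted p = 0.102; fry adjusted p = 0.0216); Ier3 rose by 2.18 (SE 0.355) and Fos by 1.83 (SE 0.312). Of 20 p53 targets 1 rose and 4 fell, with a median of -0.030, a mean of 0.077 and a test pointing down (adjusted p = 0.699). Among these, Btg2 (-0.37, SE 0.0559) and Sesn1 (-0.38, SE 0.0574) were lower, and were 0.019 and 0.012 after scaling to T-cell receptor beta genes. Counts adjusted over the list alone were the same for these lists. Replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, had 0 of 10 called by limma and 2 at an unadjusted p under 0.05 (median 0.16, or -0.10 after quantile normalization; adjusted p = 0.205; fry adjusted p = 0.0475).

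Genes of the leukemic T lineage were lower. Of 25 T-cell and thymocyte genes 20 fell and 1 rose, with a median of -0.34 that was 0.049 after scaling to T-cell receptor beta genes (adjusted p = 3.17e-06, and 4.02e-05 with that scaling, still lower than other genes; adjusted p = 0.369 with an estimated correlation; 20 lower and 1 higher adjusted over the list alone). The T-cell list was not called with the marker score as a covariate (median -0.11, adjusted p = 0.0744; 0 members called), and without knockouts 2 and 3 it was, with 14 lower and 1 higher. Rag1, which cuts DNA at antigen receptor genes, fell from 34030 ± 2190 to 22340 ± 3080 (-0.62, SE 0.0857), and was -0.23 and no longer called with that scaling (adjusted p = 0.0553). Cd7, a T- and NK-cell surface protein, rose from 14.4 ± 5.51 to 94.6 ± 35.5 (2.63, SE 0.325). Of 19 NOTCH targets 9 fell and 1 rose, with a median of -0.25 that was 0.14 after scaling to T-cell receptor beta genes (adjusted p = 0.0148, and 0.00884 with that scaling, still lower than other genes; adjusted p = 0.424 with an estimated correlation; 10 lower and 3 higher adjusted over the list alone). Ptcra, the pre-T-cell receptor alpha chain, fell by -0.62 (SE 0.0966) and stayed lower at -0.24 with that scaling. Lfng, a glycosyltransferase that modifies NOTCH, rose by 1.90 (SE 0.263). Notch1 (-0.14, SE 0.0981), Hes1 (-0.21, SE 0.0777) and Dtx1 (-0.25, SE 0.107) did not pass (adjusted p = 0.33, 0.0608 and 0.0964). Hes1 passed without control 1 (adjusted p = 0.0164) or knockout 1 (0.0252), and Dtx1 without knockout 1 (0.0395).

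MYC targets of ribosome biogenesis were lower for 19 of 25 and higher for 0 in limma (0 also at an unadjusted p under 0.05), with a median of -0.23 that was 0.16 after scaling to T-cell receptor beta genes (adjusted p = 2.82e-07, and 0.0161 with that scaling, still lower than other genes; adjusted p = 0.367 with an estimated correlation; 21 lower adjusted over the list alone). Myc itself fell from 8513 ± 994 to 5860 ± 836 (-0.54, SE 0.101) and was -0.15 with that scaling (adjusted p = 0.344). The ribosome biogenesis genes Wdr43 (-0.39, SE 0.0566) and Pes1 (-0.27, SE 0.041) were lower as deposited and 0.0030 and 0.11 with that scaling. Nuclear-encoded oxidative phosphorylation genes were lower for 17 of 36 and higher for 0 in limma (0 also at an unadjusted p under 0.05), with a median of -0.15 that was 0.24 after scaling to T-cell receptor beta genes (adjusted p = 8.1e-06, and 0.945 with that scaling; adjusted p = 0.424 with an estimated correlation; 23 lower adjusted over the list alone). Ndufb10 of complex I (-0.27, SE 0.0464) and Uqcrc2 of complex III (-0.25, SE 0.0492) turned to 0.12 and 0.14 with that scaling, and Uqcrc2 was not called without knockouts 2 and 3 (adjusted p = 0.0531). Fatty acid oxidation genes were lower for 11 of 23 and higher for 2, with a median of -0.18 that was 0.21 after scaling to T-cell receptor beta genes (adjusted p = 0.00529, and 0.147 with that scaling; adjusted p = 0.367 with an estimated correlation; 13 lower and 2 higher adjusted over the list alone). Acaa2, the mitochondrial thiolase, fell by -0.54 (SE 0.0552) and Acadvl, the very long chain acyl-CoA dehydrogenase, by -0.51 (SE 0.0587); both stayed below 0 with that scaling, at -0.15 and -0.12, and were no longer called. The 2 that rose were Eci1 (1.36, SE 0.293; 0.873 and not called without knockouts 2 and 3, adjusted p = 0.0974), an enoyl-CoA isomerase, and Acadl (0.24, SE 0.0731), the long chain dehydrogenase. Acadl was not called without control 4 or 5 (adjusted p 0.053 and 0.0562) or knockout 2 or 3 (0.0893 and 0.0589). Without knockouts 2 and 3 members called lower numbered 12 for MYC targets, 2 for oxidative phosphorylation, 8 for fatty acid oxidation and 6 for NOTCH targets (1 higher), with all 4 lists called. In the fit with the marker score 0 members of these lists were called and NOTCH targets lost the list call (adjusted p = 0.181). The score of other cell types, which rose where these lists fell, did not overlap between the acute groups (highest control -0.12, lowest knockout 0.11).

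Lists around the ATP-citrate lyase reaction were mixed in the acute arm, and none was called by camera over all libraries. Of 19 genes of acetyl-CoA and citrate supply 4 rose and 7 fell, with a median of -0.12 that was 0.26 after scaling to T-cell receptor beta genes (adjusted p = 0.157; fry adjusted p = 0.0222, pointing down; 8 lower and 4 higher adjusted over the list alone). Acss2, which makes acetyl-CoA from acetate in the cytosol, was lower (579 ± 50.3 to 482 ± 44.8; -0.26, SE 0.0837), but 0.12 with that scaling. The Acss2 call was lost without control 1, 4 or 6 (adjusted p 0.0535, 0.063 and 0.0634) or knockout 2 or 4 (0.0948 and 0.0677), and without knockouts 2 and 3 (0.0705). Pdha1, of pyruvate dehydrogenase, fell by -0.29 (SE 0.0398; 0.10 with that scaling), and Idh1, the cytosolic isocitrate dehydrogenase, rose by 0.87 (SE 0.14). Cholesterol genes numbered 2 higher and 5 lower of 24, with a median of -0.060 that was 0.33 with that scaling (adjusted p = 0.186). Without knockouts 2 and 3 the cholesterol list was called lower (median -0.12, adjusted p = 0.0239), with 2 members lower and 0 higher. Dhcr7, of the last step of cholesterol synthesis, and Insig1, which retains the sterol sensor in the ER, were lower (-0.33, SE 0.056, and -0.29, SE 0.0563) and turned to 0.061 and 0.099.

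Fatty acid synthesis genes numbered 5 higher and 3 lower of 20, with a median of -0.054 that was 0.34 after scaling to T-cell receptor beta genes, a mean of 0.19 and a test pointing down (adjusted p = 0.902). The acyl-CoA synthetase gene Acsl1 (1.67, SE 0.214) and the elongase gene Elovl7 (2.48, SE 0.327) rose. Fasn (-0.098, SE 0.101), Srebf1 (-0.071, SE 0.0658) and Srebf2 (-0.098, SE 0.0652) did not pass, with adjusted p-values of 0.511, 0.455 and 0.286. Of 10 tested LXR targets 1 rose and 0 fell, 3 and 0 at an unadjusted p under 0.05 (median 0.18, adjusted p = 0.129). Glycolysis genes numbered 6 higher and 5 lower of 21, with a median of -0.020 that was 0.37 with that scaling, a mean of 0.20 and a test pointing up (adjusted p = 0.972). The glycolysis list was called lower with the marker score as a covariate (median -0.17, adjusted p = 0.0421), with 1 member called, higher. The lactate carriers went apart: Slc16a3, known from glycolytic and myeloid cells, rose from 106 ± 25.3 to 881 ± 453 (2.93, SE 0.275), and Slc16a1 fell from 6436 ± 281 to 4714 ± 285 (-0.45, SE 0.05; -0.062 with that scaling). Histone acetyltransferases and deacetylases numbered 1 higher and 7 lower of 26, with a median of -0.053 that was 0.34 with that scaling (adjusted p = 0.132; fry adjusted p = 0.0493). Ep300, an acetyltransferase, rose by 0.56 (SE 0.0641) and Hdac2, a deacetylase, fell by -0.31 (SE 0.0526), turning to 0.082. Adjusted over the list alone these counts were the same, except that glycolysis had 6 lower. Among 5 sex-linked genes Xist rose by 1.30 (SE 0.246) and 2 fell, among them Eif2s3y (-0.44, SE 0.0917; -0.052 with that scaling, and not called without knockouts 2 and 3, adjusted p = 0.0707), with a list adjusted p of 0.335 and a median of -0.40; adjusted over the list alone 1 rose and 3 fell.

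**Figure D3:**
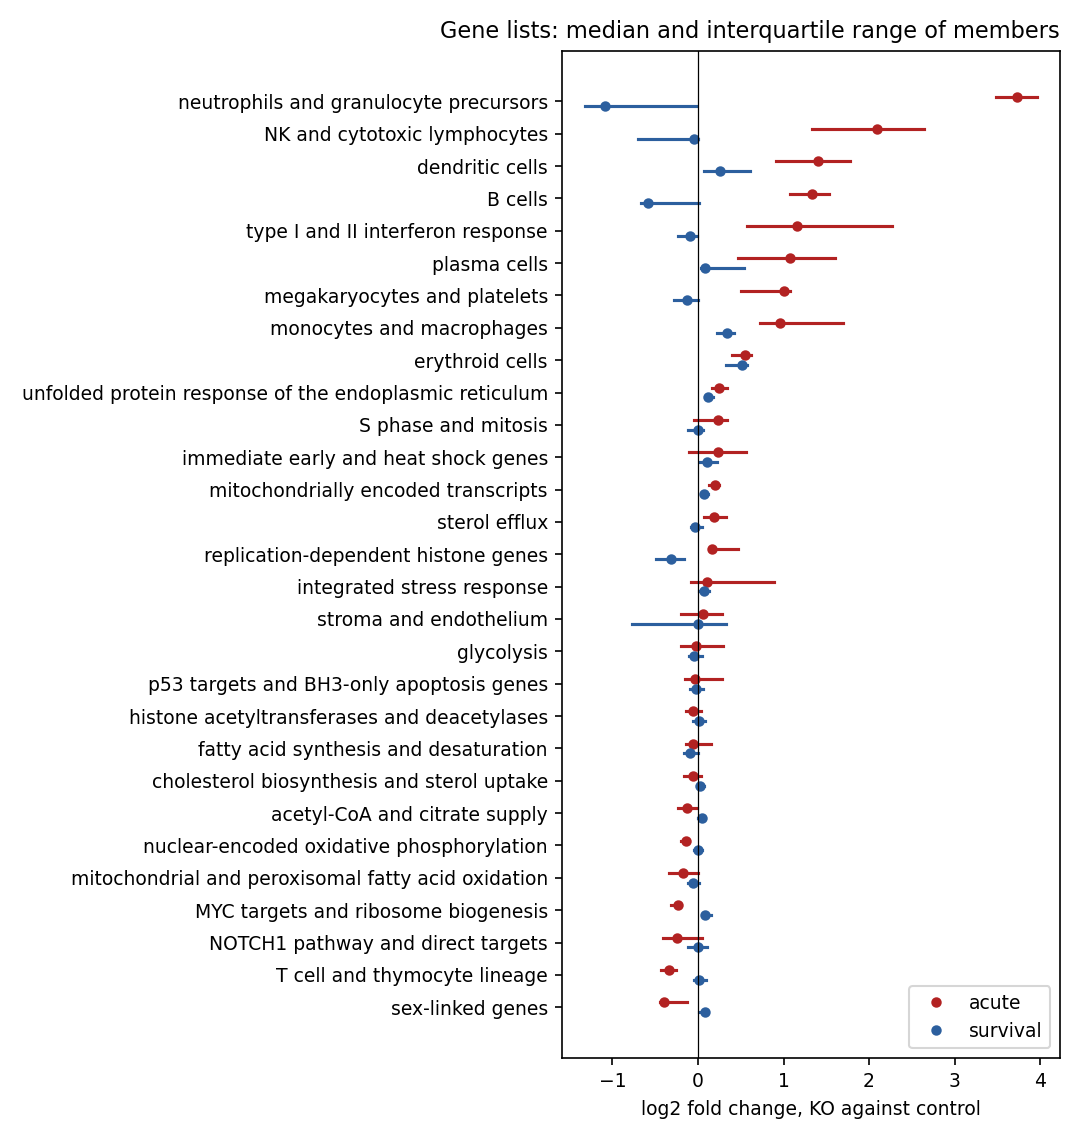
Median (point) and interquartile range (bar) of the log2 fold changes of the members of each of the 29 lists (y axis, list; x axis, log2 knockout over control), acute in red and survival in blue. The acute neutrophil median is 3.72 and the survival one -1.09; acute medians of the MYC (-0.23), oxidative phosphorylation (-0.15), NOTCH (-0.25), T-cell (-0.34) and fatty acid oxidation (-0.18) lists turn positive after scaling to T-cell receptor beta genes.

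The largest acute rises and falls lay partly outside these lists. They are given among genes with a mean of at least 100 in the higher group and no overlap, leaving out predicted genes and receptor segments. After Cstdc5 (5.04, SE 0.669), a stefin-family gene that went from 4.23 ± 3.83 to 152 ± 79.6 normalized counts, the largest rises were Upp1, uridine phosphorylase (4.89, SE 0.86), the p38-family kinase gene Mapk13 (4.89, SE 1.08), Ggt1 (4.87, SE 0.75), the coagulation factor XIII subunit gene F13a1 (4.87, SE 0.47), the mast-cell protease gene Prss34 (4.80, SE 0.46), Pik3r6 (4.70, SE 0.885) and Mmp8. Mapk13 was not called without knockouts 2 and 3 (adjusted p = 0.0732). Falls under this rule were smaller; outside it, 4732465J04Rik went from 44.1 ± 10 to 0 (-5.46, a value that depends on the pseudocount). Among the largest were the uroplakin gene Upk1b (-1.12, SE 0.154), Igfbpl1 (-1.05, SE 0.265), the surface glycoprotein gene Cd200 (-1.04, SE 0.197), Stra8 (-1.01, SE 0.182), the PI3-kinase subunit gene Pik3r3 (-1.01, SE 0.136), Ankrd37 (-0.98, SE 0.243) and Gpr83 (-0.96, SE 0.189). All 7 stayed below 0 after scaling to T-cell receptor beta genes, Ankrd37 without a call (adjusted p = 0.0544). Without knockouts 2 and 3 the calls of Igfbpl1 (adjusted p = 0.087) and Ankrd37 (0.131) were lost, and Igfbpl1 was 0.16 with the marker score as a covariate. Predicted genes were called 153 times higher and 230.0 times lower of 3128 tested.

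At the endpoint of the survival arm few genes were called between knockout and control spleens. limma called 2 of 16136 genes, Acly and Ccnd1, with 1411 at an unadjusted p under 0.05. Ccnd1, which encodes the G1 cyclin D1, rose from 285 ± 31.4 to 757 ± 236 normalized counts (SD, n = 5 and 5; 1.35, SE 0.179, adjusted p = 0.0323). Its call was lost without control 1, 2, 3 or 5 (adjusted p 0.117, 0.131, 0.148 and 0.0844) and without knockout 1 or 5 (0.0688 and 0.0825). It was also lost with the replicate number as a block (0.0525) and after scaling to T-cell receptor beta genes (0.0541). With that scaling the Ccnd1 fold change was 1.41 with a wider error (SE 0.22). Trbv26, a gene of that scaling, lay below all controls in knockouts 1 and 2 (4301 and 3719 against 4850 to 6465). The scaling may therefore not follow leukemic content in this arm. Without control 4 limma called 24 genes, 20 higher and 4 lower, without knockout 2 it called 4, and without any of the 6 libraries that end the Ccnd1 call it called 1. The groups did not overlap for 324 genes, 2.01% of those tested, where chance gives 0.79%. Myc (0.080, SE 0.0724), Notch1 (-0.33, SE 0.118), Fasn (-0.10, SE 0.134), Srebf1 (-0.057, SE 0.0803), Srebf2 (-0.14, SE 0.0904), Acss2 (-0.15, SE 0.112), Hes1 (0.0037, SE 0.0728) and Dtx1 (-0.059, SE 0.115) did not pass.

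Camera called 10 lists in the survival arm without any member called among all genes, and fry called 0 of 29, with 1 at an unadjusted p under 0.05. Adjusted over the list alone, 16 members over all lists were higher and 7 lower, at most 5 in one list. Macrophage markers had a median of 0.34 (adjusted p = 2.79e-05; adjusted p = 0.861 with an estimated correlation), and the 5 that passed adjusted over the list alone were Cd163 (0.64, SE 0.177), Vcam1 (0.56, SE 0.156), Mrc1 (0.63, SE 0.202), Csf1r (0.36, SE 0.117) and Hmox1 (0.61, SE 0.206), most of them known from resident macrophages. The monocyte markers Ly6c2 (-0.97, SE 0.476, adjusted p = 0.598) and Ccr2 (-0.19, SE 0.2, adjusted p = 0.81) lay on the other side of 0 and were not called. No test set these 2 markers against the 5. In the acute arm the 5 were called higher too (0.53 to 0.99), beside Ly6c2 and Ccr2. The acute calls of Vcam1, Mrc1 and Hmox1 were lost without acute knockout 2 or 3. Vcam1 also lost its call without acute control 1, 2, 3 or 5 or acute knockout 4, and Mrc1 without acute control 2, 3 or 5 or acute knockout 4. Without acute knockouts 2 and 3 together only Csf1r of the 5 was called (adjusted p = 0.00199), with Cd163 at an adjusted p of 0.0515. Higher lists were also the unfolded protein response (median 0.12, adjusted p = 0.00262), erythroid markers (0.52, adjusted p = 0.00268) and MYC targets (0.082, adjusted p = 0.0242), each with an adjusted p = 0.861 with an estimated correlation. Lower lists were B-cell markers (-0.59, adjusted p = 0.000518), replication-dependent histone genes (-0.32, adjusted p = 0.0173), interferon response (-0.095, adjusted p = 0.0202), neutrophil markers (-1.09, adjusted p = 0.0204), fatty acid oxidation (-0.062, adjusted p = 0.0214) and fatty acid synthesis (-0.088, adjusted p = 0.0297), each again with an adjusted p = 0.861 with an estimated correlation. Survival control 4 had a neutrophil mean of 7.22 (log2) against 8.99 to 9.19 in the other controls, and the marker scores of the groups overlapped.

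Leaving out one library ended several of these calls. Some medians shrank with their sign kept: neutrophil from -1.09 to -0.625 without knockout 5, erythroid from 0.52 to 0.225 without control 5, and interferon from -0.095 to -0.0149 without knockout 1. The neutrophil call was lost without control 1, 2, 3 or 5 (adjusted p 0.0586, 0.0609, 0.0663 and 0.0891) or knockout 2, 4 or 5 (0.304, 0.0677 and 0.345), and the MYC call without control 2 or 4 (0.154 and 0.305) or knockout 1 or 2 (0.421 and 0.131). Interferon genes were not called without control 1, 3 or 4 (0.0648, 0.112 and 0.111) or knockout 1 (0.158), and erythroid markers without control 1 or 5 (0.0586 and 0.198). Fatty acid oxidation lost its call without control 2 or 3 (0.106 and 0.0663) or knockout 1 or 5 (0.159 and 0.118), fatty acid synthesis without control 1, 3 or 5 (0.131, 0.0599 and 0.0891) or knockout 2, 3 or 5 (0.0501, 0.111 and 0.118), and histone genes without control 5 or knockout 2 (0.0747 and 0.0885). Macrophage, unfolded protein response and B-cell lists were called without each library in turn. Other splits of the survival libraries called a median of 7 lists by the same test, so a call that holds in each run does not exclude chance. Without control 4 the dendritic list (adjusted p = 0.00646), plasma-cell markers (0.0312), immediate early genes (0.0399) and cell cycle genes (0.0425) were called as well. Without knockout 1 the cell cycle (0.0254), glycolysis (0.0372) and mitochondrially encoded (0.00971) lists were called. Mitochondrially encoded transcripts were also called without control 1, 2 or 3 (0.0311, 0.0406 and 0.00381), immediate early genes without knockout 3 or 4 (0.0427 and 0.0206), and plasma-cell markers without knockout 4 or 5 (0.0175 and 0.0262).

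The remaining survival lists were not called. Medians were 0.043 for acetyl-CoA supply (adjusted p = 0.475), 0.021 for cholesterol synthesis (0.769), -0.048 for glycolysis (0.236), -0.0031 for oxidative phosphorylation (0.685), 0.075 for mitochondrially encoded transcripts (0.0821), 0.0026 for NOTCH targets (0.998), 0.076 for the integrated stress response (0.3), 0.10 for immediate early genes (0.122) and 0.011 for T-cell genes (0.524). Among markers they were 0.084 for plasma cells (0.0552), 0.26 for dendritic cells (0.272), -0.052 for NK cells (0.236), -0.0040 for stroma (0.685) and -0.13 for megakaryocytes (0.524), and the sex-linked median was 0.084 (0.685). Median, mean and test differed in sign for LXR targets (median -0.032, mean 0.031, test down, adjusted p = 0.685), p53 targets (-0.021, 0.010, up, 0.695), cell cycle genes (0.0025, -0.017, down, 0.524) and histone acetylation enzymes (0.0062, -0.0071, down, 0.998).

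The knockout changes of the acute and the survival arm differed for 3173 of 15673 genes tested in both, 1471 with a higher and 1702 with a lower fold change in survival, and 5227 at an unadjusted p under 0.05. After scaling to T-cell receptor beta genes these were 48 higher and 2659 lower, and after quantile normalization 2535 and 1523. The lowest p with a lower survival fold change belonged to Ccr2 (difference -4.55, SE 0.418), 6430548M08Rik (-3.36, SE 0.318), the interleukin-6 receptor gene Il6ra (-3.22, SE 0.325), Rassf4 (-2.77, SE 0.284) and the semaphorin gene Sema6b (-3.12, SE 0.321), all higher in acute knockouts. On the other side stood 4732465J04Rik, a gene listed at 0 in all 4 acute knockouts and at 29.5 to 58.0 in acute controls, Upb1, which acts in pyrimidine breakdown (1.04, SE 0.113), Btf3l4 (0.55, SE 0.0718), the noncoding RNA gene Zfas1 (0.78, SE 0.108) and the signaling regulator Rgs10 (0.60, SE 0.084). Without acute knockouts 2 and 3, limma called 1262 genes, and 7 with the marker score as a covariate. Across genes, which are not independent replicates, the fold changes correlated at r = -0.079 (Pearson) and -0.037 (Spearman), and at r = -0.19 among genes called in at least one arm. Ccnd1 was called higher in both arms, where chance gives 0.16, and Acly, the deleted gene, lower in both, where chance gives 0.15. With 1 survival gene called in each direction, these chance values are only the shares of genes called in the acute arm. The overlaps therefore do not decide whether the arms agree. Ccnd1 rose more in survival (difference 0.88, SE 0.236, adjusted p = 0.0119) than in the acute arm (0.48, SE 0.128), where it was not called without knockouts 2 and 3 (adjusted p = 0.225).

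Of the 29 lists, 14 had a fold change that differed between the arms by camera, 4 higher and 10 lower in survival, and 0 with an estimated correlation (smallest adjusted p = 0.301). Lower in survival were neutrophil (median difference -4.68, adjusted p = 1.26e-14), NK (-2.13, 7.49e-05), B-cell (-1.74, 2.97e-09), interferon (-1.19, 9.57e-11), dendritic (-1.07, 0.0259), megakaryocyte (-1.05, 0.0476), macrophage (-0.62, 3.55e-06), histone gene (-0.63, 0.0431), plasma-cell (-0.48, 0.0431) and cell cycle lists (-0.27, 0.0291). Higher were MYC targets (0.35, 1.06e-06), T-cell genes (0.35, 6.6e-07), NOTCH targets (0.23, 0.0367) and oxidative phosphorylation (0.17, 0.000595). Myc itself differed by 0.62 (SE 0.129, adjusted p = 0.00187). The directions of the 4 higher lists depend on scaling. Scaling to T-cell receptor beta genes moves every difference down by the same amount, as Acly shows (-0.92 to -1.26). The medians of NOTCH targets and oxidative phosphorylation then turn below 0, and those of MYC targets and T-cell genes come near 0. The lists were not tested on the contrast after that scaling.

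**Figure D4:**
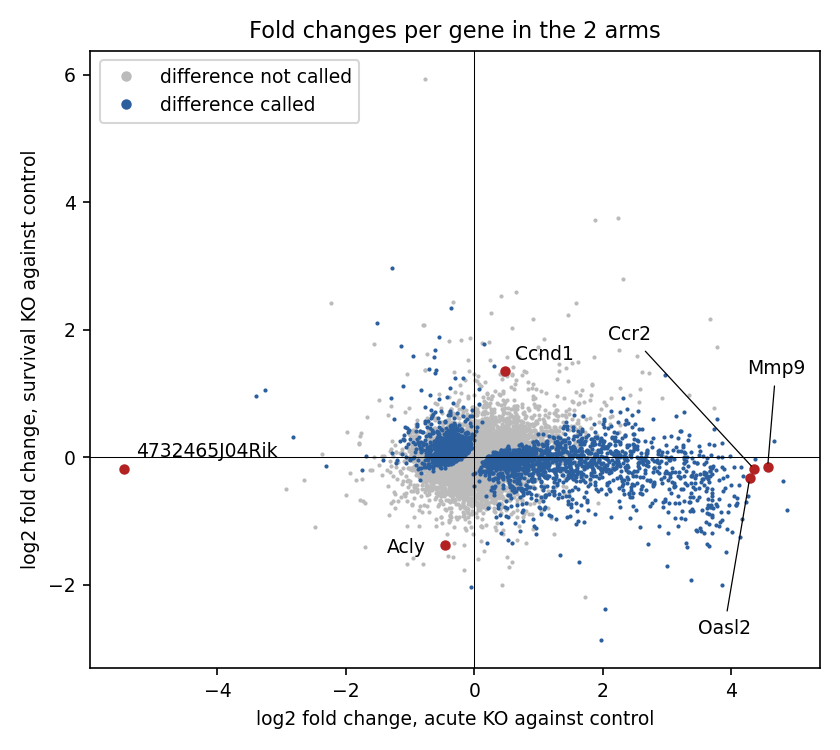
Log2 fold change of each gene tested in both tables, acute (x axis) against survival (y axis), knockout over control, with genes whose changes differ in blue and labelled genes in red; the acute position of 4732465J04Rik depends on the pseudocount, since its knockouts are listed at 0. The points spread along the acute axis, with r = -0.079 across genes; Acly lies at -0.46 and -1.38, Ccnd1 at 0.48 and 1.35, and scaling to T-cell receptor beta genes would move every acute value up by 0.39.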

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

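The tests of other cell types, of acute knockout libraries 2 and 3, of tamoxifen and of dilution were chosen only after the results were seen, and so was the test of lists on the contrast between the arms. A pair of rules picked results out: a library far from the rest of its group by Dixon's test, and a difference between the acute and the survival fold change that passed its test.

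Myeloid, B-cell and cytotoxic markers were higher in acute knockouts. A smaller leukemic share that raises every other cell type alike would give equal rises where leukemic cells add little RNA to the markers. Neutrophil markers rose by 2.44 (log2) more than B-cell markers (exact two-sided permutation p = 0.00476, n = 6 and 4, the smallest that 210 arrangements can give). They rose by 3.25 more than erythroid and by 2.27 more than macrophage markers. Under that condition, which was not tested, these values argue against an equal rise. Fold changes of members had an SD of 0.46 in the neutrophil, 0.278 in the B-cell and 1.24 in the macrophage list. Acute knockout libraries 2 and 3 alone do not account for the neutrophil rise, because the median was 3.14 without them with all 18 markers called. The macrophage, B-cell and NK medians were 0.62, 1.05 and 1.5 without them against 0.96, 1.33 and 2.09. These libraries were picked for their high marker levels, so lower medians without them follow from the choice and decide nothing. Tamoxifen itself rather than the loss of Acly stays open: no group received tamoxifen without deletion, and the survival arm, dosed long before collection, had a neutrophil median of -1.09. A candidate explanation is therefore a change in the cells of the spleen after treatment, largest for neutrophil markers, which no gate in the protocol would remove and which these bulk libraries cannot assign to Acly.

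MYC targets, oxidative phosphorylation, fatty acid oxidation and NOTCH targets were lower in acute knockouts. Dilution of leukemic RNA by RNA of other cells cannot be told apart from a change in these lists. The median of their 103 tested members went from -0.19 to 0.195 (SD 0.311) after scaling to T-cell receptor beta genes, but this scaling adds 0.388 to every gene, so any median above -0.388 turns. That test was first read as fitting dilution and then left open for this reason. By camera, which compares a list with other genes, MYC and NOTCH targets were still called lower after the scaling (adjusted p 0.0161 and 0.00884), and oxidative phosphorylation and fatty acid oxidation were not (0.945 and 0.147). The scaling shifts all fold changes alike and leaves their order unchanged. It also changes their errors (for Acly from SE 0.0747 to 0.154), on which camera depends. These calls therefore do not decide on dilution either. With the marker score in the fit the MYC, oxidative phosphorylation and fatty acid oxidation lists were still called (medians -0.292, -0.137 and -0.151) with 0 members called, and NOTCH targets were not (-0.0964, adjusted p = 0.181), in groups whose scores do not overlap. Of all 2409 genes called lower, 69 were still called lower after that scaling, 41 when the Y-linked genes set the scale. These are among the largest falls (median -0.961 against -0.301 for all), 2 of them belong to the 4 lists, and the median of all 2409 was 0.0875 (SD 0.28) after the scaling. Of the 69, 67 stayed below 0 and 1 was called with the marker score in the fit. The count was first read as excluding dilution for those genes and then left open, since genes with the largest falls decide nothing for the rest.

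The acute fall of Acly was smaller than the survival fall. Acute knockouts 2 and 3 alone do not account for it, since the difference without them was -0.758 (SE 0.179, adjusted p = 0.0114). Acly RNA from other cells in the spleen cannot be told apart from a real difference: the difference went from -0.92 (SE 0.164) to -0.66 (SE 0.259, adjusted p = 0.334) with the marker score in the fit, where the difference shrank, its error widened and 7 genes passed in all, and the scores of the acute groups do not overlap. That test was first read as excluding other cells and then left open for this reason. The time since treatment, which differs between the arms, may also matter and was not tested.

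Each count of splits or relabelings in this paragraph includes the real grouping itself. Chance can be excluded for the acute gene count, where 1 of 100 splits of the libraries gave as many as the real 5140 (highest other 14). It can also be excluded for the difference between the arms (3173, 1 of 100 relabelings, highest other 1). For the 2 survival genes 2 of 100 splits gave as many (highest other 4). One of them is Acly, the deleted gene, so this count does not decide on chance for Ccnd1. For the 17 acute lists 4 of 100 splits gave as many, under 1 in 20, although another split gave 19 and the other splits a median of 8. Camera with an estimated correlation called 0 of these lists, also 0 at an unadjusted p under 0.05. Chance cannot be excluded for the 10 survival lists, since 22 of 100 splits gave as many, the highest other gave 15 and the other splits a median of 7.

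Of 382 groups of values tested, 21 held a library far from the others, where chance gives about 1 in 20. In acute control 2, which has the highest marker score of the controls, F13a1 (187.9 normalized counts, others at most 73.6), Prss34 (62.49, others at most 24.4), Acsl1 (479.8), Mmp9 (455.4), Nkg7 (123.5), Itga2b (93.18), Il6ra (171.6) and Ngp (14140, others at most 7350) stood high. Notch1 was high in acute control 1 (84930) and Gzma low there (6486), Upb1 high in acute control 3 (503.3), Cd163 high in acute control 4 (133.2) and Sesn1 high in acute knockout 4 (1280). Survival control 4 stood apart for Trbv1 (1367, others at most 389) and in the mean log2 values of the oxidative phosphorylation (11.4), neutrophil (7.216), dendritic (6.037) and NK lists (6.238). Survival control 5 was high for Srebf1 (2656) and 6430548M08Rik (198), and survival knockout 2 for Csf1r (1051).

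The survival less acute fold change (log2) passed its test for 64 of the named genes and 14 lists, and for 0 lists with an estimated correlation (smallest adjusted p = 0.301). Among members of the neutrophil and macrophage lists it was -5.14 for Ly6c2, -4.9 for Ngp, -4.73 for Mmp9, -4.6 for S100a9, -4.55 for Ccr2, -4.41 for Mmp8 and -0.628 for Csf1r. Among members of the interferon, NK, B-cell, plasma-cell, dendritic and megakaryocyte lists it was -4.62 for Oasl2, -4.2 for Oas2, -4.04 for Gzmb, -3.21 for Nkg7, -1.82 for Jchain, -1.67 for Flt3, -1.61 for Cd22, -1.4 for Cd74, -1.36 for Itga2b and 0.378 for Gzma. Members of the T-cell, NOTCH and MYC lists gave 0.516 for Rag1, -2.94 for Cd7, -2.19 for Lfng, 0.622 for Myc, 0.535 for Wdr43 and 0.301 for Pes1.

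Members of the metabolic lists gave 0.4 for Pdha1, -0.808 for Idh1, 0.413 for Dhcr7, -1.7 for Acsl1, -3.03 for Elovl7, 0.523 for Acaa2, -2 for Eci1, -3.34 for Slc16a3, 0.47 for Slc16a1 and 0.232 for Uqcrc2. Members of the cell cycle, stress, p53, histone acetylation, immediate early and sex-linked lists gave -0.767 for Mki67, -0.647 for Plk1, 0.35 for Btg2, 0.312 for Sesn1, -0.307 for Sel1l, -0.622 for Ep300, 0.404 for Hdac2, -1.48 for Cebpb, -2.15 for Ier3, -1.6 for Fos, -1.49 for Xist and 0.525 for Eif2s3y. Genes on none of the lists were -0.923 for Acly, 0.878 for Ccnd1, 2.7 for Trbv1, 0.494 for Hilpda, -5.7 for F13a1, -5.17 for Prss34, -3.36 for 6430548M08Rik, -3.22 for Il6ra, -3.12 for Sema6b, -2.77 for Rassf4, 1.17 for Upk1b, 0.967 for Stra8, 1.28 for Pik3r3, 0.952 for Gpr83, 1.04 for Upb1, 0.552 for Btf3l4, 0.784 for Zfas1 and 0.6 for Rgs10. For 4732465J04Rik the fitted difference of 5.27 depends on the pseudocount, since acute knockouts are listed at 0. Median differences of the lists were 0.165 for oxidative phosphorylation, 0.227 for NOTCH targets, 0.351 for MYC targets, 0.346 for T-cell genes, -0.274 for the cell cycle, -1.19 for interferon, -1.74 for B cells, -0.481 for plasma cells, -0.625 for macrophages, -4.68 for neutrophils, -1.07 for dendritic cells, -2.13 for NK cells, -1.05 for megakaryocytes and -0.627 for histone genes. Scaling to T-cell receptor beta genes moves all these differences down alike, with Acly going from -0.923 to -1.26. Small positive ones then turn below 0, among them oxidative phosphorylation, NOTCH targets and Uqcrc2. Leaving out 1 library ended the calls of Hilpda (acute control 2, 3, 4 or 5, acute knockout 2, 3 or 4, survival control 1, 2, 4 or 5, or survival knockout 2, 3 or 4; adjusted p 0.0528 to 0.102), Gzma (acute knockout 2 or 3, 0.0515 and 0.0535) and Csf1r (acute knockout 2 or 3, 0.0718 and 0.0715).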

How the results depend on the processing

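Scaling to T-cell receptor beta genes and leaving out acute knockouts 2 and 3 together were chosen only after the results were seen; the planned tests on whole reads were not run, because whole reads were not recovered. Where no cause is given, the cause was not tested. Acly in the survival arm kept its direction and call under all 21 alternatives; leaving out 1 library in turn gave -1.48 to -1.26 there, -0.519 to -0.383 in the acute arm and -1.03 to -0.804 for the difference between the arms. Leaving out 1 library gave 3693 to 5444 acute genes, 1 to 24 survival genes, 2239 to 3585 genes whose change differed, 14 to 17 acute lists and 6 to 12 survival lists (6 without survival control 5 or knockout 2). With a stricter threshold by construction, limma called 2823 acute and 1 survival genes at an adjusted p under 0.01 and 1426 acute genes at a fold of at least 2. Survival genes numbered 6 with a pseudocount of 8, 4 with a filter of 50, 4 with robust eBayes, 11 with array weights and 1 with T-cell receptor beta scaling. With an estimated correlation 0 acute and 0 survival lists were called, and fry called 0 survival lists. The replicate number as a block gave 3294 acute and 2363 differing genes and 2 survival genes, 1 of them shared, with the Ccnd1 call lost (adjusted p = 0.0525); correlations of like-numbered libraries ran from -0.0662 to 0.142 (acute) and from -0.0204 to 0.128 (survival), so the numbers do not pair the libraries. Fold changes correlated across genes at -0.186 among genes called in at least 1 arm. The marker score as a covariate, which does not overlap between the acute groups, left 150 acute genes (140 higher, 10 lower), 11 acute lists, 4 survival genes, 7 differing genes and an Acly difference of -0.66. It turned Igfbpl1 to 0.161, Pck2 to -0.354, Xbp1 to -0.0523, Itga2b to -0.192, Vwf to -0.125, Scart1 to -0.791, Edem1 to 0.0851, Hmox1 to -0.0647, and the medians of glycolysis to -0.166, unfolded protein response to -0.0366, erythroid to -0.769 and megakaryocyte markers to -0.332, with glycolysis and erythroid lists called lower (adjusted p 0.0421 and 2.45e-07). T-cell receptor beta scaling, which shifts all acute fold changes by 0.388, gave Acly -0.0686 and turned Acss2 to 0.124, Pdha1 to 0.1, Dhcr7 to 0.0611, Insig1 to 0.0992, Sqle to 0.109, Scd2 to 0.0433, Ndufb10 to 0.12, Uqcrc2 to 0.14, Wdr43 to 0.00296, Pes1 to 0.114, Nop58 to 0.0521, Btg2 to 0.0192, Sesn1 to 0.012, Hdac2 to 0.0818, Btg1 to 0.0886, Btf3l4 to 0.107, Edem1 to 0.152 and Mcm6 to 0.214. Without acute knockouts 2 and 3 there were 2137 acute genes (1414 higher, 723 lower), 1262 differing genes and an erythroid median of 0.0188. The cholesterol list was then called lower (-0.116). Among the calls lost were Acss2, Uqcrc2, Chac1, Atf6, Gzma, Eci1 and Eif2s3y (adjusted p 0.0705, 0.0531, 0.0793, 0.0709, 0.0793, 0.0974 and 0.0707). Also lost were Mapk13, Igfbpl1, mt-Co1, Ankrd37, Mcm6, Ccnd1, Acadl, Itga2b, Scart1, Vwf and Edem1 (adjusted p 0.0732 to 0.587). What depth limits was not tested: a rough figure is 16.6 to 23.7 M reads per library, from a step that varies by gene. Recovery of the smallest simulated changes was 32% (acute) and 18% (survival) with these numbers of libraries.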

Other observations

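Tests of receptor segments, of Xist and Y-linked genes, and of hypoxia genes were chosen only after the results were seen. Trbv26 was the leading T-cell receptor beta segment in every acute library. It made up 64.2 to 67.9% of the summed normalized counts of all Trbv segments in acute controls (n = 6) and 61.8 to 66.2% in acute knockouts (n = 4). Trbv1 made up 2.73 to 4.09% and 3.11 to 3.97% in the same groups. In survival controls Trbv1 made up 3.05 to 15.2% (15.2% in control 4 alone), and in survival knockouts 8.93 to 42.0%. Trbv26 made up 54.0 to 66.3% in survival controls and 31.9 to 59.8% in survival knockouts. In survival knockout 2 Trbv1 (42.0%) was above Trbv26 (31.9%), and in knockout 1 they were near each other (39.6 and 41.2%). Trbv1 went from 530 ± 470 to 2628 ± 1770 normalized counts (SD, n = 5 and 5; log2 difference 2.34, SE 0.492; exact two-sided permutation p = 0.0159; limma adjusted p = 0.185, or 0.0236 without control 4). Scart1, a scavenger receptor gene known from gamma-delta T cells, went from 16.9 ± 17.1 to 182 ± 102 in the survival arm (3.75, SE 0.649; exact two-sided permutation p = 0.00794; limma adjusted p = 0.128, or 0.0168 without control 4). In the acute arm it was called higher (2.24, SE 0.691), a call lost without control 4 or 6 (adjusted p 0.0504 and 0.0552) or knockout 2 or 3 (0.0803 and 0.0848), and -0.79 with the marker score as a covariate.

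Cells with another rearrangement may have replaced part of the leukemia in survival knockouts, which would lower Trbv26. Trbv26 differed by -0.213 (log2, SE 0.131; exact two-sided permutation p = 0.238). Its normalized counts in knockouts 1 and 2 (4301 and 3719) lay below all controls (4850 to 6465), and those in the other knockouts (5376 to 6227) did not. The share of Trbv26 falls by arithmetic when Trbv1 rises, so it does not decide, and the hypothesis is neither borne out nor excluded.

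Xist and Y-linked genes were both present in every library, as female host cells beside a male leukemia might give. Over the 10 survival libraries Xist rose with the marker score of other cells (Pearson r = 0.898, permutation p = 0.00037, adjusted p = 0.00074 over 2 relations; Spearman rho = 0.939, permutation p = 0.00019; r = 0.909 without the 2 libraries farthest from the median score). The Y-linked genes, which the hypothesis has falling as the score rises, gave r = 0.308 (permutation p = 0.387, adjusted p = 0.387; rho = 0.224, permutation p = 0.535). The predicted fall was not seen, which the rule written for this test counted against the hypothesis. Without the 2 farthest libraries r was -0.332, so the sign rests on few libraries and this part is neither borne out nor excluded there. In the acute arm the Y-linked genes averaged -0.354 (log2) in knockouts, while Xist rose by 1.30. Their mean log2 values were 9.3, 8.891, 9.137 and 9.62 in knockouts 1 to 4, against 9.472 to 9.729 in controls. Marker score and treatment cannot be separated in that arm, and no test was run there. Sexes of host and leukemia are not given in the labels.

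Hilpda, a lipid droplet gene that also responds to hypoxia, fell from 299 ± 23.8 to 165 ± 19.7 acutely (-0.85, SE 0.0998) and stood at 297 ± 16.9 and 235 ± 48.3 in the survival arm (-0.36, SE 0.133, adjusted p = 0.431). Lower hypoxia genes were a hypothesis from Hilpda and Ankrd37. A hypoxia list without these 2 genes was not called (medians -0.0777 and 0.0375, adjusted p = 0.879 and 0.423 by camera over 4 tests). Of its 18 acute members 6 were called higher and 6 lower. The test pointed up in both arms, which the rule written for it counted against lower hypoxia genes. The other tests of the 4 were of a list of PPAR targets, not called without the members that led to it (medians -0.13 and -0.0437, adjusted p = 0.35 in both). Lower hypoxia genes were therefore not borne out, and without a call in either direction they were not excluded.

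4732465J04Rik was the only gene listed at 0 in all 4 acute knockouts and above 10 in all 6 acute controls (29.5 to 58.0). It stood at 44.4 to 71.0 in survival controls and 37.6 to 55.2 in survival knockouts, and what the locus does was not tested.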
